A study of Arabidopsis thaliana with 2 samples.

How the data were processed

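Total RNA from the 4 youngest rosette leaves of Arabidopsis thaliana at developmental stage 6.50 was measured on 1 array for the BOUNTIFUL line and 1 array for its background, the wild-type accession Ws-0. Plants of both genotypes were grown on compost in a glasshouse at 23 °C with 16 h of light per day. The labels describe BOUNTIFUL as carrying an activation tag, an insert with an enhancer, at a locus they call BOU in the Ws-0 background. Biotin-labelled cRNA was hybridised to the Affymetrix ATH1 array, which holds 22810 probe sets on each array, 64 of them controls and 22746 for Arabidopsis transcripts. The array platform reads each transcript through a probe set and summarises it as 1 brightness value.

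The deposited values were intensity signals on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version was not given in the sources used here. The mean signal after trimming 2% of probe sets at each end was 100.0 on both arrays, so the values had been scaled to a common level before deposit. No further scaling between the arrays was applied for the main values. Detection calls were not used here, and background was judged from the signals alone.

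Log2 ratios were computed as BOUNTIFUL minus Ws-0 of log2(signal + pseudocount). The pseudocount was the 20th percentile of all signals, 7.77 units. Folds of genes are on this scale, which understates the difference of low signals, while log2 ratios and folds of control probe sets are taken from the signals with no pseudocount. Control probe sets were left out, and a probe set was kept where its mean signal over both arrays reached the median of that mean, 39.9 units. The filter left 11373 probe sets. A probe set was counted as higher or lower from a 2-fold difference, a log2 ratio of 1 or -1. The share of higher probe sets among those was given with an exact (Clopper-Pearson) 95% interval, which covers counting only and treats probe sets as independent.

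Each group held 1 array, so no difference was tested, no p-value was computed and no spread between plants could be estimated. The number of arrays limits the precision of every value.

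Probe sets were named from a platform annotation of 2016, with symbols updated through the gene table of the TAIR10.1 assembly. Of the Arabidopsis probe sets, 13513 (59.4%) had 1 gene, 503 had several and 8730 were not listed. Of those with 1 gene, 13484 were matched in the gene table and 29 kept the annotation's symbol. Probe sets with several genes or not listed stayed in the counts and were not named. Among passing probe sets 6025 had 1 gene, 232 had several and 5116 were not listed. Several probe sets of 1 gene were averaged, which gave 5990 measured genes.

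Apart from members of groups chosen after the data were seen, the genes named were set by a rule written before the data were examined. It took the 15 highest and the 15 lowest log2 ratios among passing probe sets with 1 gene, members of gene lists and members of the runs of neighbouring genes. For a list outside the central 95% of random lists, up to 4 members in the direction of its median and up to 2 in the other direction were named, and for every other list up to 2 members. A set of 40 gene lists with 705 entries was written at the same time, from textbook pathways, hormone responses, stress responses and markers of other tissues. Of these entries 95 had a named probe set and 59 passed the filter, while 610 had no probe set named here, so most lists were read through few members. For the 10 lists with at least 3 measured members, the median log2 ratio was set against 10000 random lists in which each member was replaced by 1 of the 100 genes nearest to it in brightness. The percentile describes these arrays and is not a test of the genotypes. The 15 lists with 1 or 2 measured members are given as values, and 15 lists had none.

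The activation tag led to a further planned comparison, in which the highest mean log2 ratio over runs of 3 and of 5 neighbouring measured genes was set against 10000 shuffles of gene order. The gene table gave the order of 5914 genes, through their chromosome and start position. Distances between genes were not used. Technical controls were the hybridisation spikes, the ratios of 3' to 5' probe sets of actin, GAPDH and ubiquitin, and the control probe sets for Bacillus subtilis genes.

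Alternatives fixed before the data were examined were median centring, quantile normalisation, loess of the log2 ratio on mean signal with a span of 0.3, no pseudocount, a pseudocount at the 40th percentile (24.8 units), no filter, a filter at the 75th percentile of mean signal, leaving out probe sets whose suffix marks possible cross-hybridisation, and the brightest probe set of a gene in place of the mean. Choices made after the data were seen were scalings that set the newer or the older hybridisation spike probe sets equal on both arrays, 25 families of genes that share the letters of their symbol (at least 5 measured genes each), plastid-encoded genes and their split by function, the lowest run of neighbouring genes, 20 redraws of the random lists for lists outside the central 95%, and the leaf senescence list with no filter. In this last choice 3 of the 4 genes had BOUNTIFUL signals below the highest Bacillus subtilis control signal, so its value is given with that limit.

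The list and run procedures were checked on simulated data built by shuffling the measured log2 ratios. Among 200 random lists of 4 of the 5990 genes with no shift, 5.5% lay outside the central 95%, and 7.5% of 200 lists of 8 did. With a planted log2 shift of 1, these shares were 93.5% and 100%. Lists of 3, the size of several lists read here, were not checked, and the shuffling removed any link between log2 ratio and brightness. A planted shift of 2 over 5 neighbours among 5914 genes was located in 94% of 50 trials. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.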

Results

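Expression in the youngest rosette leaves was compared between the activation-tagged gain-of-function line BOUNTIFUL and wild-type Ws-0, to ask which transcripts differ in the mutant. There was 1 array per genotype and no replicate. Each difference below is therefore between a pair of RNA samples and has no replicate check. The median signal was 38.9 units on the BOUNTIFUL array and 39.0 units on the Ws-0 array. The locus of the tagged gene was not given in the labels, so its level is not reported here.

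The gene with the highest log2 ratio among probe sets assigned to 1 gene in the main setting was the subtilisin-like protease gene SBT4.12 (AT5G59090), with a signal of 357 units in BOUNTIFUL and 9.94 in Ws-0, a log2 ratio of 4.36. CSLA01 (AT4G16590), of the cellulose synthase-like A family that makes mannan backbones, reached 1080 units against 91.9, a log2 ratio of 3.45. The defensin gene LCR69 (AT2G02100) was higher by a log2 ratio of 2.96, with 704 units against 83.8. XTH32 (AT2G36870), of the xyloglucan endotransglucosylases that cut and rejoin wall xyloglucan, was higher by 2.68, with 894 units against 133. MPC (AT3G19350) was higher by 3.04. The other 10 of the 15 highest genes bear no symbol beyond their locus. AT1G06000 had 653 units against 69.1, an 8.60-fold difference. The others were AT4G22212 (3.76 in the main setting), AT1G54020 (3.41), AT5G42860 (3.39), AT4G23680 (3.29), AT1G31690 (3.18), AT3G05400 (3.14), AT5G44400 (3.06), AT3G53980 (2.71) and AT4G25780 (2.66). For 4 of the 15, SBT4.12, AT4G22212, AT5G42860 and AT3G05400, the Ws-0 signal lay in the range of the Bacillus subtilis control probe sets, so the size and order of these log2 ratios rest on the pseudocount. That of AT4G22212 was 5.65 with none and 2.53 with one at the 40th percentile, and those of SBT4.12 were 5.17 and 3.46 and of AT5G42860 5.14 and 2.22.

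The gene with the lowest log2 ratio was AT1G64360, at 48.1 units in BOUNTIFUL and 1562 in Ws-0, a log2 ratio of -4.81. AT1G67860 followed at -4.30, AT3G19550 at -4.04, AT1G13470 at -3.50 and AT4G32920 at -3.25. AT4G24450, to which the gene table gives the symbol PWD that it also gives to AT5G26570, had 42.6 units against 413, a log2 ratio of -3.06. AT1G67865 and AT1G67870, the next measured genes after AT1G67860 on the chromosome, were lower by log2 ratios of -2.40 and -2.34, and AT1G67870 still had 367 units in BOUNTIFUL against 1895 in Ws-0. The remaining genes among the 15 with the lowest log2 ratios were AT3G61210 (-2.93), AT2G36970 (-2.87), AT3G62960 (-2.62), AT1G24575 (-2.51), AT2G05540 (-2.45), AT4G01390 (-2.29) and AT5G59670 (-2.22). For AT1G67860, AT3G19550, AT1G13470, AT4G32920, AT3G62960 and AT2G05540 the BOUNTIFUL signal, from 5.53 to 19.7 units, lay in the range of the controls, so the size and order of their log2 ratios rest on the pseudocount too. That of AT4G32920 was -4.43 with none and -2.25 with one at the 40th percentile. All 30 genes kept at least a 2-fold difference in the same direction under every scaling, pseudocount and filter that retained them. For the scalings and filters this followed from their choice as the most extreme genes, so it is no check of them.

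**Figure D1:**
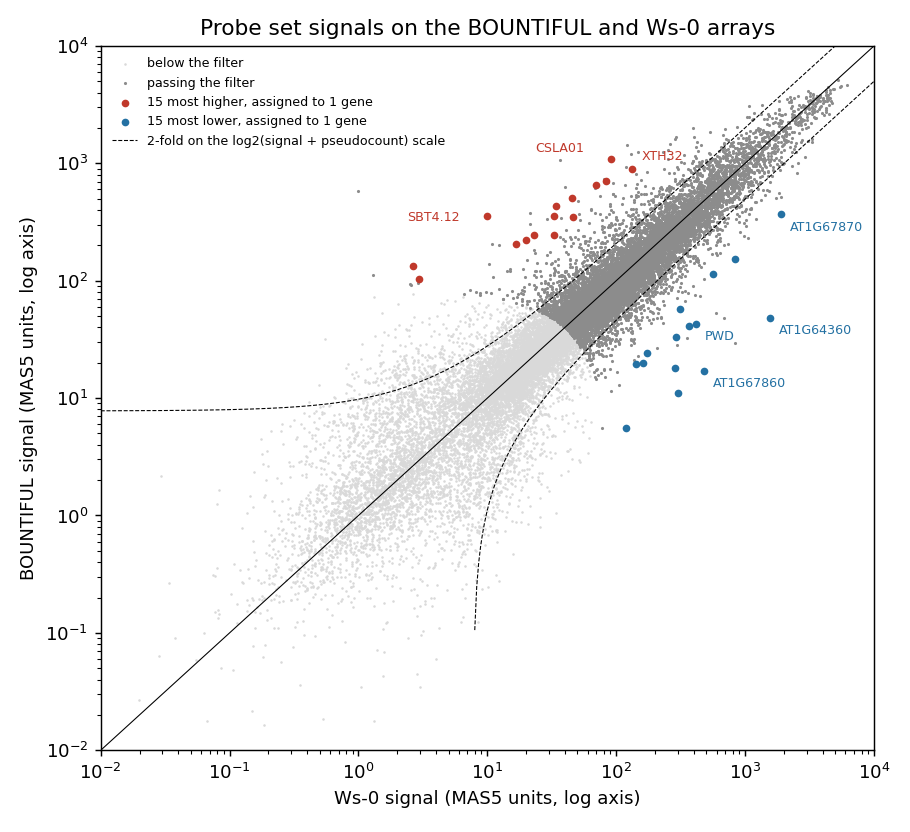
Signal of each probe set on the BOUNTIFUL array (vertical, MAS5 units, log axis) against the Ws-0 array (horizontal, MAS5 units, log axis), with probe sets below the filter in light grey, passing ones in dark grey, and the 15 highest and 15 lowest single-gene probe sets in red and blue. The solid line marks equal signals, the dashed lines mark a 2-fold difference after the pseudocount, and AT1G64360 (48.1 against 1562 units) lies far below while SBT4.12 (357 against 9.94 units) lies far above.

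Large differences were also present among probe sets that the annotation does not assign to 1 gene. Probe set 258795_at, which is not listed, had 581 units in BOUNTIFUL and 0.98 in Ws-0, a signal in the range of the controls. Its log2 ratio of 6.07 rests on the pseudocount and was 9.21 with none and 4.56 with one at the 40th percentile. Probe set 247192_at, assigned to several genes, had 1061 units against 36.7, a log2 ratio of 4.59. The lowest unlisted probe sets were 264638_at, with a log2 ratio of -4.51, and 262832_s_at, with -3.62.

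Over the 11373 passing probe sets, 527 were at least 2-fold higher and 453 at least 2-fold lower in BOUNTIFUL, together 8.62%. The higher ones made up 53.8% of these (exact 95% interval 50.6 to 56.9%). Of the probe sets with 1 gene, 235 were higher and 196 lower. At least 4-fold differences were counted for 100 higher and 41 lower probe sets, and at least 8-fold differences for 30 and 11. The log2 ratio had a median of -0.06 and an SD over probe sets of 0.62. Over all 22746 Arabidopsis probe sets, those below the filter included, log2(signal + pseudocount) of the arrays correlated with Pearson r = 0.952. Probe sets are not independent replicates. For 33 genes with a pair of measured probe sets, the log2 ratios of the pair differed by a median of 0.21, and 1 pair differed by over 1.

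The balance of higher and lower probe sets rested on how the arrays were scaled. Hybridisation spikes, transcripts added to the hybridisation mix, are read by 9 newer and 9 older probe sets, and all of these had log2 ratios below 0. Both sets read the same few transcripts, bioB, bioC, bioD and cre, from 1 hybridisation per array, so the probe sets are not independent. The newer ones had a mean of -0.35 (SD over probe sets 0.080, range -0.46 to -0.24), a 1.28-fold difference, and the older ones a mean of -0.55 (SD 0.18, range -0.87 to -0.35), a 1.46-fold difference. With the newer spikes set equal, 1118 probe sets were higher and 203 lower, a share of 84.6% higher, and the median log2 ratio of passing probe sets was 0.27 in place of -0.06. With the older spikes set equal, 1663 were higher and 131 lower, a share of 92.7%, with a median of 0.45. A log2 ratio between about -0.35 and 0 changes sign under the first of these scalings, and one between about -0.55 and 0 under the second. Both were chosen after the data were seen. The 3' to 5' ratios of actin, GAPDH and ubiquitin were all higher in BOUNTIFUL, by at most 1.12-fold. On the deposited scale, the log2 ratios of the control probe sets for these genes lay on both sides of 0. They ran from -0.003 to 0.16 for actin, from 0.08 to 0.30 for GAPDH and from -0.38 to -0.15 for ubiquitin. Unlike the spikes, these genes showed no common shift, which does not settle which scaling is right. The control for 25S rRNA had 26.9 units in BOUNTIFUL and 54.5 in Ws-0, and that for 5S rRNA had 127 and 76.0.

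**Figure D2:**
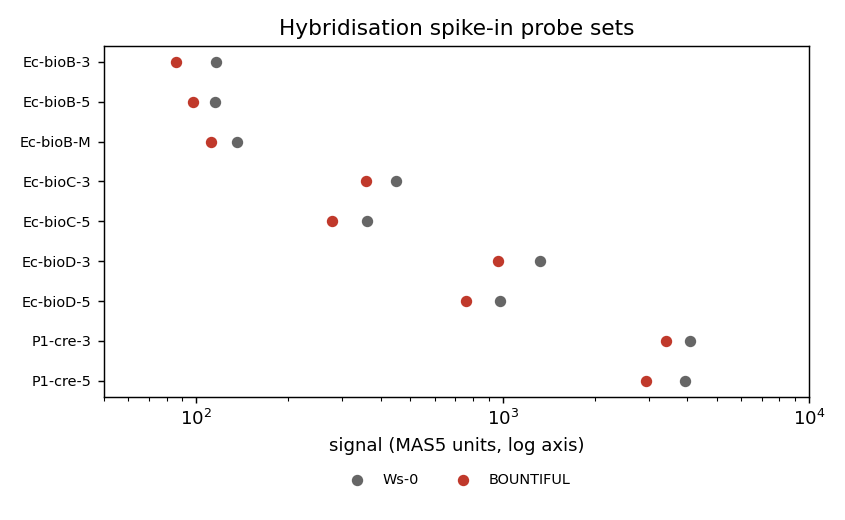
Signals of the 9 newer hybridisation spike probe sets (horizontal, MAS5 units, log axis) on the Ws-0 array in grey and the BOUNTIFUL array in red, 1 point per array. Each red point lies to the left of its grey point, with a mean log2 ratio of -0.35.

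All 4 measured members of the flavonoid and anthocyanin list had log2 ratios above 0, and 1 was at least 2-fold higher in BOUNTIFUL, with a median log2 ratio of 0.82 at the 98.9th percentile of matched random lists. DFR (dihydroflavonol reductase, AT5G42800) had 129 units against 32.8, a log2 ratio of 1.75, UF3GT (AT5G54060), an anthocyanin glycosyltransferase, 0.95, UGT78D2 (AT5G17050) 0.70 and UGT78D1 (AT1G30530) 0.28. The antenna list of 17 genes held 3 measured ones, all for the minor antenna protein CP29, with log2 ratios above 0 and none at least 2-fold higher. LHCB4.2 (AT3G08940) had a log2 ratio of 0.70, LHCB4.3 (AT2G40100) 0.63 and LHCB4.1 (AT5G01530) 0.22, a median of 0.63 at the 97.7th percentile. The antenna median lay at the edge of the central 95%, since 20 redraws of the random lists gave percentiles of 97.475 to 97.9, on both sides of it.

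The cell wall loosening list was represented only by expansins, which loosen the wall during cell growth, and these went both ways. EXPA4 (AT2G39700) and EXPA15 (AT2G03090) were higher, with log2 ratios of 1.22 and 1.15. EXPA8 (AT2G40610) had -0.04, turning positive under the other scalings, and EXPA16 (AT3G55500) -0.43. The list's median of 0.56 lay at the 98.2nd percentile, and at the 96.3rd with no filter, where XTH33 entered. Expansins as a family did not stand apart, since the 5 measured EXPA genes, a grouping chosen after the data were seen that adds EXPA9 (AT5G02260) at -0.98, had a median of -0.04 at the 51.5th percentile.

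The 3 measured genes of aliphatic glucosinolate synthesis had log2 ratios below 0, and 1 was at least 2-fold lower in BOUNTIFUL. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation, had 1005 units against 2561, a log2 ratio of -1.34. GSTU20 (AT1G78370) had -0.64 and AT2G31790 -0.62. The median of -0.64 lay at the 2.46th percentile, at the edge of the central 95%. Over 20 redraws of the random lists it lay between the 2.18th and 2.73rd percentile, on both sides of that edge. The median became -0.29 with the newer and -0.10 with the older spikes set equal. Of indole glucosinolate synthesis, UGT74B1 was measured, at -0.60.

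**Figure D3:**
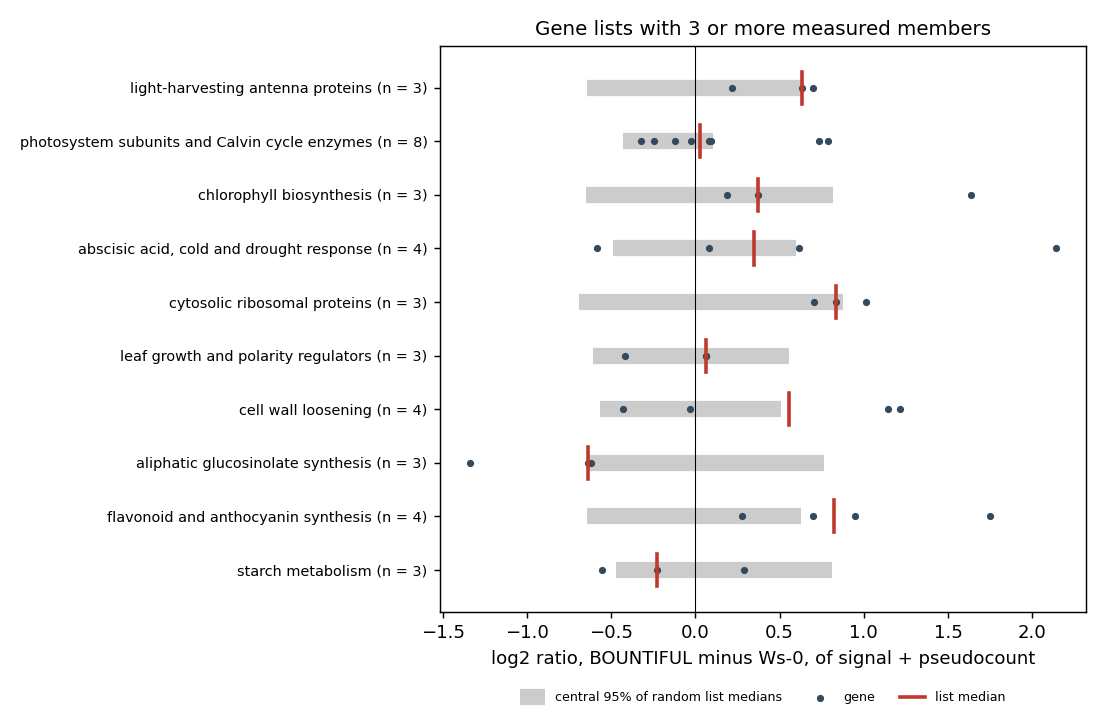
Log2 ratio (BOUNTIFUL minus Ws-0, horizontal) of each measured gene as a dot and of the list median as a red line, for the 10 gene lists with at least 3 measured members, with n the number of genes. The grey band is the central 95% of medians of 10000 random lists matched on brightness. The flavonoid and cell wall loosening medians (0.82 and 0.56) lie above their bands, and the antenna and aliphatic glucosinolate medians (0.63 and -0.64) lie at the edge of theirs.

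The other 6 lists with at least 3 measured members lay inside the central 95%. The 3 measured cytosolic ribosomal protein genes had log2 ratios above 0, with a median of 0.84 at the 96.9th percentile. AT2G19730 had a log2 ratio of 1.01 and PGY1 (AT2G27530) 0.84. Photosystem subunits and Calvin cycle enzymes had a median of 0.03 over 8 genes (94.2nd percentile), with 4 above and 4 below 0, from -0.32 to 0.79 for PSAN, and PSAE-1 at 0.74. With the newer spikes set equal, all 8 were above 0. In chlorophyll biosynthesis (median 0.37, 85.3rd percentile, 3 genes), PORB, a protochlorophyllide oxidoreductase, had 1.64 and CHLM 0.37. Abscisic acid, cold and drought genes had a median of 0.35 over 4 genes (88.5th percentile), with 3 above 0 and 1 below, at -0.58. The dehydrin gene LTI30 had 2.14 and COR15B 0.62. Leaf growth and polarity genes had a median of 0.06 (70.9th percentile, 3 genes), with PHV at -0.42 and YAB3 at 0.06. The starch metabolism median was -0.23 (16.3rd percentile, 3 genes) and turned to 0.11 with the newer and 0.30 with the older spikes set equal. APL3 had -0.55 and SBE2.2 0.29.

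Among lists with 1 or 2 measured members, the largest values were those of the jasmonate-responsive defensin genes. PDF1.2 (AT5G44420) had 242 units in BOUNTIFUL against 54.8, a log2 ratio of 2.00, and PDF1.2b (AT2G26020) 546 against 94.5, a log2 ratio of 2.44. The senescence list was represented by PPDK (AT4G15530), at -1.64. The touch and wound response list was represented by STZ (AT1G27730), a zinc finger gene, at -1.31. In the cytokinin list the response regulator RR16 (AT2G40670) had -1.30. Of the cell cycle and replication list, PRL, a subunit of the MCM helicase, had 0.85 and the kinase gene AUR1 0.43. The gibberellin receptor genes GID1A and GID1C had -0.68 and -0.27. Flowering time was represented by AGL24 at 0.78 and SNZ at -0.64. The stomatal lineage gene FMA had -0.52, and the dark and starvation genes MCCA and MCCB had -0.39 and 0.01. The remaining values, each within 0.2 of 0, were those of GI (evening clock, -0.08), HAT2 (auxin, -0.10), EIN3 and RTE1 (ethylene, -0.11 and 0.10), PYE (iron, -0.12) and AT1G04770 (sulfur, -0.18).

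The 15 lists with no measured member covered salicylic acid defence, heat shock, morning clock genes, brassinosteroids, meristem and boundary genes, vascular tissue, cuticle and wax, phosphate, nitrate, oxidative stress enzymes, chromatin regulators and markers of flowers, pollen, seeds and roots. Markers of other tissues with a named probe set were below the filter on average. The floral gene UFO had a mean signal over both arrays of 1.73 units, the pollen actin ACT12 had 4.45, and the root hair expansins EXPA7 and EXPA18 had 19.6 and 25.6.

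Because an activation tag carries an enhancer, neighbouring genes were examined for a shared higher signal. The highest run of 3 measured neighbours was AT5G44400 (3.06), AT5G44410 (0.14) and PDF1.2 (2.00), with a mean log2 ratio of 1.73. A mean as high arose in 57.5% of 10000 shuffles of gene order. The highest run of 5 was AT4G23670 (1.18), AT4G23680 (3.29), AT4G23730 (-0.30), AT4G23740 (0.56) and AT4G23820 (2.47), with a mean of 1.44, which 11.9% of shuffles reached. Neither run stood apart from shuffled gene order. Only the 5914 ordered genes with a named probe set that passed the filter could enter a run. Genes between them that were unnamed or below the filter were skipped.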

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

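The scalings on the newer and on the older hybridisation spikes were chosen after the data were seen, and the other alternatives for the counts, fixed lists and named genes were planned. No paired analysis was possible because each genotype had 1 array, and for the same reason no array could be left out. Of the main 527 higher and 453 lower probe sets, median centring kept 527 and 380, quantile normalisation 518 and 421, loess 524 and 389, the newer spikes 527 and 203, and the older spikes 527 and 131 in the same direction. The share of higher probe sets, 53.8% in the main setting, was 61.5% with median centring, 59.8% with loess, 57.2% with a pseudocount at the 40th percentile, 84.6% with the newer spikes set equal and 92.7% with the older. No filter gave 948 higher and 799 lower probe sets, the filter at the 75th percentile 322 and 251, the newer spikes 1118 and 203, and the older spikes 1663 and 131. The counts under the filters differ because more or fewer probe sets enter, and those under the spike scalings because every BOUNTIFUL signal is multiplied by 1 factor. Among list medians, the antenna list was at 0.70 with median centring and 0.98 and 1.18 with the newer and older spikes, the ribosomal list at 1.19 and 1.38 with these, and the aliphatic glucosinolate list at -0.57 with median centring and -0.29 and -0.10 with the newer and older spikes. The starch list was at 0.30 with the older spikes. The leaf growth list was at 0.13 with median centring, 0.11 with quantile normalisation, 0.13 with loess, 0.068 with no pseudocount and 0.38 and 0.55 with the newer and older spikes. For the share under loess and under the other pseudocount, the cause was not tested. A list value was taken as moved when it left the range of the list's main gene values, which are not replicates. A list's percentile can differ where genes move apart, where its members change or where a filter changes the genes it is matched to. With the filter at the 75th percentile, the abscisic acid, cold and drought list went from 88.5 to 82 with the same 4 members and median. Over all alternatives, some of which only redraw the random lists, the percentile was 98.6 to 99.99 for the flavonoid list (10 alternatives) and 96.3 to 98.6 for cell wall loosening (10). It was 97.49 to 98.1 for the antenna (11) and 1.08 to 2.79 for aliphatic glucosinolates (11). Redraws of the random lists alone gave the antenna list 97.475 to 97.9 and the aliphatic glucosinolate list 2.18 to 2.73. The highest run of 3 neighbours was reached by 41.7 to 83.5% of shuffles and that of 5 by 6.15 to 33.9% under 7 alternatives. Signals of the 27 Bacillus subtilis control probe sets reached 21.9 units in BOUNTIFUL and 16.7 in Ws-0, so low signals of that size cannot be told from background.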

Other observations

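The tests of scaling, RNA degradation, leaf age, spikes, gene loss, symbol families, plastid genes and the lowest run were chosen after the result was seen. The comparison of the highest runs of neighbours was planned, but its reading as a test of the enhancer was written after its values were seen. Several groups of genes that no list covered also stood apart. Of 5 measured genes of glycosyl hydrolase family GH9, endoglucanases that act on the cell wall, 4 were at least 2-fold higher in BOUNTIFUL. GH9C2 had 542 units against 142 (log2 ratio 1.87), GH9B8 1.79, GH9B13 1.69 and GH9B7 1.39, while GH9A3 had -0.37. Their median of 1.69 lay at the 99.99th percentile of matched random lists, but the 19 genes with symbols starting in GH that were present with no filter had a median of 0.05 (79.1st percentile). That grouping by letters is not limited to GH9 and takes in genes below the filter, so it does not show GH9 alone. A median of GH9 genes alone with no filter is not given here. GH9B13 (72.6 units in BOUNTIFUL against 17.1) and GH9B8 (109 against 25.9) had Ws-0 signals below the filter's threshold. Their mean signals passed it through BOUNTIFUL, while GH9A3 (35.5 against 48.1) passed through Ws-0. How far the GH9 median rests on the filter was therefore not tested. All 5 measured beta-tubulin genes had log2 ratios above 0, and 2 were at least 2-fold higher, from 0.78 for TUB5 to 1.93 for TUB1, with a median of 0.82 at the 99.6th percentile. Of 7 beta-glucosidase genes the median was 0.60 (99.7th percentile), with BGLU15 at 1.96, BGLU16 at 1.61 and BGLU33 at -1.23, but the 20 genes present with no filter had a median of 0.23 (98.9th percentile). Of 8 autophagy genes, the ATG8 genes and ATG3, 7 were below 0 and 1 was at least 2-fold lower, with a median of -0.55 (0.27th percentile). ATG8E had 38.6 units against 109 (-1.33), and ATG8H had 0.03. Of 8 cytochrome P450 genes, nearly all of the CYP71B group, 7 were below 0 and 1 was at least 2-fold lower, with a median of -0.61 (0.14th percentile), but the median was -0.17 over 26 genes at the 2.95th percentile with no filter, and it lay at the 23.8th with the filter at the 75th percentile. With the newer spikes set equal, 6 of the 8 cytochrome P450 genes were below 0, with a median of -0.31, and the autophagy median was -0.21. With the older spikes set equal these medians were -0.14 and -0.02. The remaining 20 of 25 symbol families lay between the 2.64th and 96.2nd percentile in the main setting. Some of these left the central 95% under an alternative. UGT genes lay at the 1.81st percentile with the filter at the 75th percentile, RALFL genes at the 97.6th with no filter and GSTU genes at the 2.13th with no pseudocount. Of random lists, drawn gene by gene with no regard to family, 5% would lie outside the central 95%. Genes of a family can be alike in sequence and control, so this share need not hold for families, and it was not measured for them.

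Sugar transporter genes of the SWEET family went both ways in the main setting, and the family median lay at the 61.5th percentile, with SWEET13 at -0.84. SWEET17, SWEET3 and SWEET16 were higher, with log2 ratios of 1.96, 1.51 and 1.05, while SWEET11, which exports sucrose for phloem loading, had 1142 units against 2896, a log2 ratio of -1.34. Plastid-encoded genes were split by function, with some genes in neither set and no random lists for the split. Of 27 genes for photosystem, cytochrome b6f and Rubisco subunits, 24 were below 0, with a median of -0.34. Of 19 genes for plastid RNA polymerase and ribosomal proteins, 14 were above 0, with a median of 0.14. The counts take each gene as a separate reading, though plastid genes may share a transcript. How well the labelling captured plastid RNA was not measured. With the newer spikes set equal the medians of the 27 and the 19 genes became 0.01 and 0.48, and with the older ones 0.20 and 0.66. All 69 plastid-encoded genes together had a median of -0.21 (6.99th percentile), which turned to 0.14 with the newer spikes and 0.33 with the older.

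Medians above 0 of GH9 and beta-tubulin genes with a median below 0 of autophagy genes formed the first pattern that was weighed. For GH9 the median covers only genes that passed the filter, and its dependence on the filter was not tested. Array scaling that depends on brightness is argued against, since the largest log2 shift that loess or quantile scaling gave a measured gene of these families was 0.085, against a smallest absolute median of 0.55. A single factor over the whole array moves genes nearly alike, with dim ones moved somewhat less because of the pseudocount. It thus bears on the sign of the autophagy median, -0.02 with the older spikes set equal. It bears little on the place of that median below genes matched on brightness, at the 0.35th percentile there. A large difference in RNA degradation is argued against by the 3' to 5' ratios of actin, GAPDH and ubiquitin. These were all higher in BOUNTIFUL, but by at most 1.118-fold, so a small difference stays open. Younger leaves in the BOUNTIFUL pool may be a source of it: the ribosomal protein list lay at percentile 96.92 and only 1 senescence gene passed the filter. With no filter, 4 senescence genes were read and all were below 0, with a median of -0.83 at the 0.08th percentile. Most of their BOUNTIFUL signals lay in the range of the Bacillus subtilis controls. Leaf age and genotype therefore cannot be told apart. An effect of the tagged gene stays open and untested, with 1 array per genotype.

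The lower hybridisation spikes on the BOUNTIFUL array formed the second pattern. Over all 18 newer and older probe sets the log2 ratios had an SD of 0.167, and the means of the 2 sets differed by 0.193, so a single factor for every spike cannot be told apart from shifts that differ between probe sets. A difference of this kind may stem from the amount or labelling of RNA or from a larger share of RNA read by the array, and no value here separates these. The scaling chosen sets whether 53.8%, 84.6% or 92.7% of the 2-fold different probe sets count as higher.

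The third pattern was a run of neighbouring measured genes with lower signals, AT1G67860 (17.0 units against 480), AT1G67865 (153 against 841) and AT1G67870 (367 against 1895), with a mean log2 ratio of -3.01 that 0.09% of 10000 shuffles of gene order reached. The lower of the BOUNTIFUL signals of AT1G67865 and AT1G67870 was 6.989 times the highest Bacillus subtilis control signal, and for AT1G67860 the ratio was 0.773. Each gene was read by 1 probe set, and signal from a related transcript was not measured, so loss of the genes from the BOUNTIFUL genome and a low level cannot be told apart. Shared control of the run may be a candidate explanation and was not tested.

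An enhancer acting on several neighbours of the tag would predict a run of higher genes. The highest runs of 3 and of 5 were reached by 57.5% and 11.86% of shuffles. Such a run could also have been missed, since 59.4% of probe sets were assigned to 1 gene and fewer still passed the filter, which left 5914 ordered genes.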
